A study of Aspergillus flavus with 3 samples.

How the data were processed

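Poly-A RNA from Aspergillus flavus mycelium grown in shaken potato dextrose broth at 30 °C and 200 rpm was sequenced in 3 libraries, 1 each for PDB alone, PDB + 5-AC and PDB + GA. Per the labels' protocols, each RNA was an equal-weight pool of 3 original samples, the kit was an Illumina TruSeq RNA kit, fragments measured about 380 bp with a spread of 50 bp, and reads averaged 115 bp. The age of the cultures is not given in the sources used here. Groups were taken from the treatment labels, and the table's columns were matched to samples through their titles. Pooling averages the original samples within a medium, so the spread between cultures cannot be estimated.

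Reads were aligned with TopHat 1.3.1 and Bowtie and quantified with Cufflinks 1.2.0, per the submitters' processing notes, which give no parameters. Per the file headers, the authors deposited FPKM values for each locus and library, a log2 fold change, a q-value and a call of different expression for each agent against PDB. The genome build and annotation, and the test behind the q-values, are not given in the sources used here. The deposited q-values were taken as they stand. In the deposited table, calls coincide with q-values under 0.05, and the largest q-value of a called locus is 0.0500 for 5-AC and 0.0493 for GA. The deposited log2 fold changes equal the log2 ratios of the deposited FPKM within 1.31e-05 and carry no pseudocount. A second deposited table assigns 476 genes to 55 secondary metabolism clusters and describes them. Its FPKM are the same as in the full table. How genes were assigned to clusters is not given in the sources used here.

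FPKM values are not counts, so no count model was fitted to compare media, and with 1 library per medium no test of a difference between media was run. Counting error at the estimated depths was simulated or bounded, and the positions of genes were set against shuffles. Ratios were computed as differences of log2(FPKM + 1) for annotated genes with at least 1 FPKM in at least 1 library (11118 of 13485). A difference of at least 1 on that scale is called 2-fold. The loci without an annotated gene were left out of the counts. A value of exactly 0 can be a failed estimate. For example, 5 loci are listed at 0 in PDB with at least 100 FPKM in both other libraries, so a 0 is reported only as a listed value. Loci shorter than 430 bp, the mean fragment plus its spread, have unstable FPKM: these 1165 loci hold 47.2% of the FPKM sum in PDB, 51.1% with 5-AC and 28.0% with GA. Among the 582 measured genes of that length 47.6% differed by 2-fold between 5-AC and PDB, against 13.7% of the others. Loci with the same coordinates (218) share fragments, and the kit does not mark strand, so overlapping genes on opposite strands cannot be told apart.

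Depth was estimated because the files give no counts. Among genes under 0.3 FPKM, the commonest ratio between 2 libraries was taken as the ratio of their 1-fragment values (1.09 for PDB to 5-AC in 81 of 152 genes, 0.671 for GA to 5-AC in 61 of 168, each within 3%). The smallest product of FPKM and locus length among 11 loci at those ratios in all 3 libraries was taken as 1 fragment. These depths are estimates, and they ignore introns and effective lengths. They mean that 1 FPKM over 1 kb stands for about 6 to 10 fragments, so values under 1 FPKM rest on a few fragments.

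Gene lists, 31 in number, were fixed before the data were examined, 4 by locus identifier from general knowledge (aflatoxin, cyclopiazonic acid, kojic acid, global and developmental regulators) and the rest by words in the gene descriptions. Descriptions exist only for the 476 cluster genes, of which 330 say more than hypothetical protein. Of the reference gene table given for this organism (assembly ASM901741v1), 0 rows carry the deposited locus tags, so names come only from the deposited cluster table. The kojic acid and regulator loci are not paired with names there and are reported as groups. The lists of cytoplasmic and mitochondrial ribosomal proteins, heat shock proteins and chaperones, DNA repair, DNA replication, histones and chromatin modifiers, respiratory chain, glycolysis, cell wall synthesis and proteasome matched no described gene. Lists with fewer than 3 measured members were given no median: sugar transporters (2) and amino acid transporters (2) had none past 2-fold, nor had the single measured genes of oxidative stress defence, sterol synthesis, plant polysaccharide hydrolases and proteases. The single gene of pyrimidine metabolism was at least 2-fold higher with 5-AC and is listed at 0 in PDB. Glutathione S-transferases and fatty acid beta-oxidation had no measured gene.

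For each list or cluster with at least 3 measured genes, the median log2 ratio was set against the medians of 10000 random lists of the same size and the same make-up by expression decile. For lists drawn from descriptions the random lists came from the 221 described and measured cluster genes. A percentile describes these libraries only. The random lists hold scattered genes, whereas the genes of a cluster are neighbours. Genes named in the text were chosen by a rule set before the data were examined. Per comparison with PDB, it takes the 10 largest ratios in each direction among described genes at 10 FPKM or more in the higher library, the 2 largest and 1 smallest member of each described list, the members of the 4 identifier lists and the backbone genes of the 5 clusters with the largest absolute median. Outside the rule, AFLA_053870, AFLA_101690 and AFLA_139460 were named after their values were seen. Of genes without a name, the single largest on the log2(FPKM + 1) scale in each direction per comparison with PDB is given, among genes at 10 FPKM or more in the higher library and above 0 in both; these too were chosen after their values were seen.

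The scripts were tested on simulated libraries drawn as Poisson counts from the PDB levels at the estimated depths, over 10733 genes. In them 200 genes were changed, all at 5 FPKM or more in PDB, so the calling rates do not cover lower genes. For 5-AC against PDB, 100% of 48 genes raised 4-fold and 98.1% of 52 genes lowered 4-fold were called. Genes changed exactly 2-fold lie on the threshold, and 39.6% of 53 raised and 44.7% of 47 lowered were called. Alternatives were the pseudocount, the filter on low values, rescaling by the median or the upper quartile, and a 4-fold size. Chosen after seeing the data were adding loci without a gene, leaving out loci under 430 bp and leaving out genes listed at 0. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.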

Results

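The transcriptome of Aspergillus flavus mycelium was measured in 3 culture media. A. flavus is a filamentous fungus that makes aflatoxins, cyclopiazonic acid and other secondary metabolites, and the strain is the sequenced isolate NRRL3357. One medium was potato dextrose broth (PDB) alone, one was PDB with 5-azacytidine (5-AC) at 1 mM, and one was PDB with gallic acid (GA) at 1% (w/v). 5-AC is a cytidine analogue known as an inhibitor of DNA methyltransferases, and GA is a phenolic acid of plant tissues. Each medium has 1 library, made from RNA pooled from 3 original samples, so no value below has a replicate error and no difference has a replicate check. The deposited table lists 13485 annotated genes and 1025 loci with no annotated gene, in FPKM, which scales fragments by locus length and library size. Of the annotated genes, 11118 reached 1 FPKM in at least 1 library and are called measured here. Depth was estimated from the steps between the lowest FPKM values, at about 6390000 mapped fragments for PDB, 6970000 for PDB + 5-AC and 10390000 for PDB + GA.

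The title of the series poses the question of how the fungus responds to each agent, which the comparisons of PDB + 5-AC and PDB + GA with PDB address. Differences are described by size alone. A gene counts as different when its log2(FPKM + 1) differs by at least 1 between 2 libraries, which is 2-fold on that scale. Genes are also ranked on that scale, which understates the change of genes near or under 1 FPKM. Folds given for single genes are plain ratios of FPKM, and no fold is given for a gene listed at 0 in either library. The authors' own calls are quoted as such. Locus coordinates are on the deposited scaffolds, counted from 1, and the genome build is not given in the sources used here.

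With 5-AC, genes of several secondary metabolism clusters stood higher than in PDB alone, among them 4 neighbouring genes of cluster 35. Over all 319 measured cluster genes, 32 were at least 2-fold higher and 34 at least 2-fold lower. Together these made up 20.7% of the cluster genes, against 15.3% of the 10799 genes in no cluster. The 3 loci listed for kojic acid synthesis stood lower. The ferulate-5-hydroxylase gene AFLA_101730 went from 96.8 FPKM in PDB to 581 FPKM with 5-AC (6.002-fold), and the cytochrome P450 gene AFLA_101720 from 21.7 to 107 FPKM (4.95-fold). The gene of an NRPS-like enzyme, AFLA_101700, went from 160 to 852 FPKM (5.34-fold) and the NmrA-like gene AFLA_101710 from 358 to 1392 FPKM (3.89-fold). NRPS stands for nonribosomal peptide synthetase, a class of enzymes that assemble peptides without ribosomes. All 4 are called in the authors' deposited table, with q-values from 0.000935 for AFLA_101730 to 0.0422 for AFLA_101710.

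Across the genome, 624 measured genes were at least 2-fold higher and 1097 at least 2-fold lower with 5-AC than in PDB. The median gene lay at a log2 ratio of -0.20. With the median set to 0, 844 genes were higher and 743 lower, which takes the lower share from 63.7% to 46.8%. Among annotated genes, the authors' deposited table calls 109 higher and 120 lower. Counting error at the estimated depths, simulated with no true difference, put 26 of 10533 genes past 2-fold in this comparison. That simulation holds neither the unstable FPKM of short loci nor failed estimates. Of the 1721 genes past 2-fold, 277 were under 430 bp and 292 were listed at 0 in PDB or with 5-AC. On the log2(FPKM + 1) scale, the largest ratio upward among genes at 10 FPKM or more in the higher library and above 0 in both belonged to a gene without a deposited name, AFLA_125990 (EQ963481, positions 720844 to 722573), at 0.811 FPKM in PDB and 58.8 FPKM with 5-AC. The largest in the other direction on that scale was AFLA_117330 (EQ963485, positions 422682 to 424965), at 556 FPKM in PDB and 14.3 FPKM with 5-AC.

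Of the 55 deposited clusters, 38 had at least 3 measured genes. With 5-AC, 7 of them had a median log2 ratio above the central 95% of random gene lists matched on size and expression. Below it lay 1. Lists of scattered genes would put about 0.95 on each side. Cluster genes are neighbours, and neighbouring genes often moved together outside the clusters too, as described below. Blocks of neighbours may thus pass these limits more often than scattered genes, so 0.95 is not their chance level. The same holds for the cluster counts with GA and for GA against 5-AC. Cluster 35 (EQ963484, positions 1195973 to 1209611) had a median of 2.25 over 5 genes, with 4 of them at least 2-fold higher. Its other member, the alcohol dehydrogenase gene AFLA_101690, stood at 34.8 FPKM in PDB and 47.0 FPKM with 5-AC. Cluster 27 (EQ963472, positions 2641483 to 2658105) had a median of 1.29 over 3 measured genes. Its polyketide synthase gene AFLA_082150 went from 25.5 to 98.2 FPKM (3.85-fold), and polyketide synthases build the carbon chains of many fungal metabolites. Cluster 52 (EQ963481, positions 1310210 to 1330062) had a median of 0.78 over 7 genes that went both ways. Its efflux pump gene AFLA_128040 stood at 3.98 FPKM in PDB and 15.5 FPKM with 5-AC, and its polyketide synthase gene AFLA_128060 at 6.09 and 11.2 FPKM. Clusters 1, 17, 21 and 43 were the others above, with medians of 0.46, 0.58, 0.48 and 0.45. In cluster 21, which holds genes described as similar to those of gliotoxin synthesis, 7 of 23 measured genes were at least 2-fold higher and 2 lower. Cluster 6 was the one below, at -1.47 over 3 measured genes.

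Among the other described genes at 10 FPKM or more, those with the largest ratios upward with 5-AC included the alpha/beta hydrolase gene AFLA_090180 (103 to 356 FPKM, 3.44-fold) and the N-hydroxyarylamine O-acetyltransferase gene AFLA_116260 (2.59 to 11.7 FPKM, 4.54-fold). The HHE domain gene AFLA_002840 (5.33 to 20.9 FPKM, 3.93-fold) and the multidrug transporter gene AFLA_066740 (7.90 to 23.9 FPKM, 3.03-fold) were in the same set. Of these 4, the authors' deposited table calls only AFLA_090180, with a q-value of 0.0442. The largest ratios downward belonged to the flavin-containing polyamine oxidase gene AFLA_118340, at 30.4 FPKM in PDB and 4.04 FPKM with 5-AC (7.52-fold lower), and the oligopeptide transporter gene AFLA_022880, at 384 and 85.2 FPKM (4.51-fold lower). The authors' deposited table calls both. An MFS transporter gene, AFLA_112890, followed at 18.0 and 4.83 FPKM, then an acyl transferase gene, AFLA_096440, at 33.3 and 9.83 FPKM, and an FAD-dependent oxidoreductase gene, AFLA_100330, at 18.2 and 5.39 FPKM. The oligopeptide transporter gene AFLA_064260 of cluster 21 stood at 542 FPKM in PDB and 196 FPKM with 5-AC, and the alcohol dehydrogenase gene AFLA_121590 at 51.3 and 17.4 FPKM. None of these last 5 is called for 5-AC in the authors' deposited table.

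The gene lists fixed before the data were examined gave the following for 5-AC. The 26 measured aflatoxin genes had a median log2 ratio of -0.48, or -0.29 relative to the median gene, at percentile 3.05 of matched random lists. Of them 7 were at least 2-fold lower and none was at least 2-fold higher, and the authors' deposited table calls none. With a filter at 5 FPKM, 13 genes stayed, with a median of -0.29 at percentile 41.5, while a pseudocount of 5 gave percentile 0.710 and no filter a lower one still, both below the central 95%. The 3 cyclopiazonic acid genes had a median of 0.47 (percentile 92.4) with none past 2-fold. The 3 kojic acid loci were all at least 2-fold lower, with a median of -1.39, or -1.19 relative to the median gene (percentile 0.385). The most abundant of them stood at 7926 FPKM in PDB and 3033 FPKM with 5-AC, and 1 of the 3 is called in the authors' deposited table, at 739 and 90.4 FPKM. Of 15 loci listed as global and developmental regulators, 13 differed by less than 2-fold. One of them was higher (12.5 to 40.7 FPKM) and one lower (106 to 30.1 FPKM), and both are called in the authors' deposited table. The 40 measured backbone enzyme genes, the synthases that set each cluster's product, had a median of 0.14 (percentile 97.7 among described cluster genes), with 3 at least 2-fold higher and none 2-fold lower. With a filter at 5 FPKM the percentile was 86.9, with a pseudocount of 5 it was 95.97, and without a filter the median was -0.0161 at percentile 42.3, so none of these left the list outside the central 95%.

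Lists drawn by words of the gene descriptions cover the deposited cluster genes alone, since the other genes have no description. With 5-AC, the 13 cytochrome P450 genes had a median of -0.45 (percentile 5.01), 1 higher and 2 lower by 2-fold, from AFLA_101720 down to AFLA_121610 at 9.22 FPKM in PDB and 1.83 FPKM with 5-AC. The 14 MFS transporter genes had a median of 0.00 (percentile 80.8), 3 higher and 2 lower. The 2 with the largest ratios were AFLA_004260, at 0.332 and 4.67 FPKM, and the Liz1/Seo1-type gene AFLA_053830, at 0.112 and 3.28 FPKM. The 8 Zn(II)2Cys6 transcription factor genes had a median of -0.26 (percentile 32.6) and none differed by 2-fold. The medians of the 3 ABC transporter genes (0.30, percentile 69.7), the 6 aromatic catabolism genes (0.20, percentile 76.0), the 3 conidiation genes (-0.53, percentile 11.1) and the 3 iron and siderophore genes (-0.09, percentile 55.1) lay inside the central 95% of random lists.

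**Figure D1:**
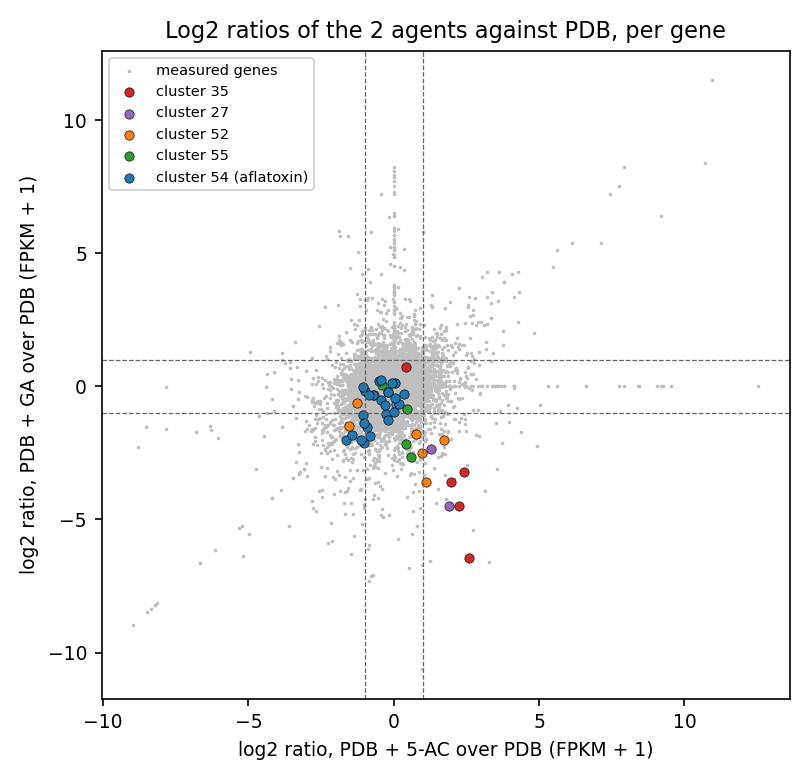
Each point is 1 of 11118 measured genes, with the log2 ratio of PDB + 5-AC to PDB on the x axis and of PDB + GA to PDB on the y axis, both on FPKM + 1; dashed lines mark 2-fold. In cluster 35, 4 genes lie at the lower right, above 1.9 with 5-AC and below -3.2 with GA, while the aflatoxin genes lie near or below 0 on both axes.

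With GA, genes of several secondary metabolism clusters stood lower than in PDB. These included cluster 35, the cyclopiazonic acid genes and the middle stretch of the aflatoxin cluster, while a smaller set of cluster genes stood higher. The same 4 genes of cluster 35 were among them. AFLA_101730 went from 96.8 FPKM in PDB to 0.126 FPKM with GA (770-fold lower), AFLA_101720 from 21.7 FPKM to a listed 0, AFLA_101700 from 160 to 16.2 FPKM (9.82-fold lower) and AFLA_101710 from 358 to 28.3 FPKM (12.6-fold lower). The polyketide synthase gene AFLA_082150 of cluster 27 went from 25.5 to 0.188 FPKM (135-fold lower). Values under 1 FPKM rest on a few fragments, so the 770-fold and 135-fold sizes are uncertain. In cyclopiazonic acid synthesis, the hybrid PKS/NRPS gene AFLA_139490 went from 34.4 to 4.63 FPKM (7.43-fold lower) and the dimethylallyl tryptophan synthase gene AFLA_139480 from 807 to 179 FPKM (4.52-fold lower). The authors' deposited table calls all 7 genes, with q-values up to 0.0206.

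Across the genome, 756 measured genes were at least 2-fold higher and 1127 at least 2-fold lower with GA than in PDB, and the median gene lay at -0.01. Among annotated genes, the authors' deposited table calls 132 higher and 257 lower. Simulated counting error alone put 18 of 10533 genes past 2-fold in this comparison, again without unstable short loci or failed estimates. Of the 1883 genes past 2-fold, 280 were under 430 bp and 296 were listed at 0 in PDB or with GA. The cluster genes took a larger part than the rest, since 31.03% of the 319 measured cluster genes differed by 2-fold against 16.5% of the 10799 genes in no cluster. With 5-AC the shares were 20.7% and 15.3%, and the shares were not matched on expression. Of the cluster genes past 2-fold with GA, 31 were higher and 68 lower. Under the same limits and on the same scale, the largest ratio upward was that of AFLA_062300 (EQ963477, positions 2033622 to 2034978), a gene without a deposited name, at 1.00 FPKM in PDB and 300.4 FPKM with GA. Downward it was that of AFLA_075240 (EQ963472, positions 795552 to 796037), at 446 FPKM in PDB and 1.82 FPKM with GA. By plain ratio AFLA_101730 was further down, but its GA value rests on a few fragments.

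With GA, 2 of the 38 clusters had a median above the central 95% of random lists and 9 below it. With a filter at 5 FPKM, 28 clusters had at least 3 measured genes, of which 4 lay above and 6 below. The 9 were clusters 20, 23, 27, 35, 42, 48, 52, 54 and 55. Cluster 35 had a median of -3.61, cluster 27 of -2.35, cluster 52 of -1.78, cluster 55 of -1.51 and cluster 23 of -1.11. Cluster 55 (EQ963478, positions 2257028 to 2277863) holds the 3 cyclopiazonic acid genes and an MFS transporter gene, AFLA_139460, which stood at 337 FPKM in PDB and 345 FPKM with GA. In cluster 52 the polyketide synthase gene AFLA_128060 went from 6.09 to 1.06 FPKM (5.74-fold lower). In cluster 23 the cytochrome P450 gene AFLA_066930 went from 25.0 to 3.62 FPKM (6.91-fold lower), and 8 of 15 measured genes were at least 2-fold lower. In cluster 43, whose median lay inside the random range, the DUF636 domain gene AFLA_116570 went from 168 to 22.3 FPKM (7.57-fold lower). The authors' deposited table calls AFLA_128060, AFLA_066930 and AFLA_116570. Clusters 10 and 17 lay above, with medians of 1.14 over 3 genes and 1.06 over 9. In cluster 17 (EQ963483, positions 1670504 to 1697608), the FAD-dependent oxidoreductase gene AFLA_053820 went from 22.2 to 85.1 FPKM (3.84-fold) and the transporter gene AFLA_053830 from 0.112 to 9.01 FPKM. The polyketide synthase gene of that cluster, AFLA_053870, stood at 4.22 FPKM in PDB and 4.30 FPKM with GA.

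**Figure D2:**
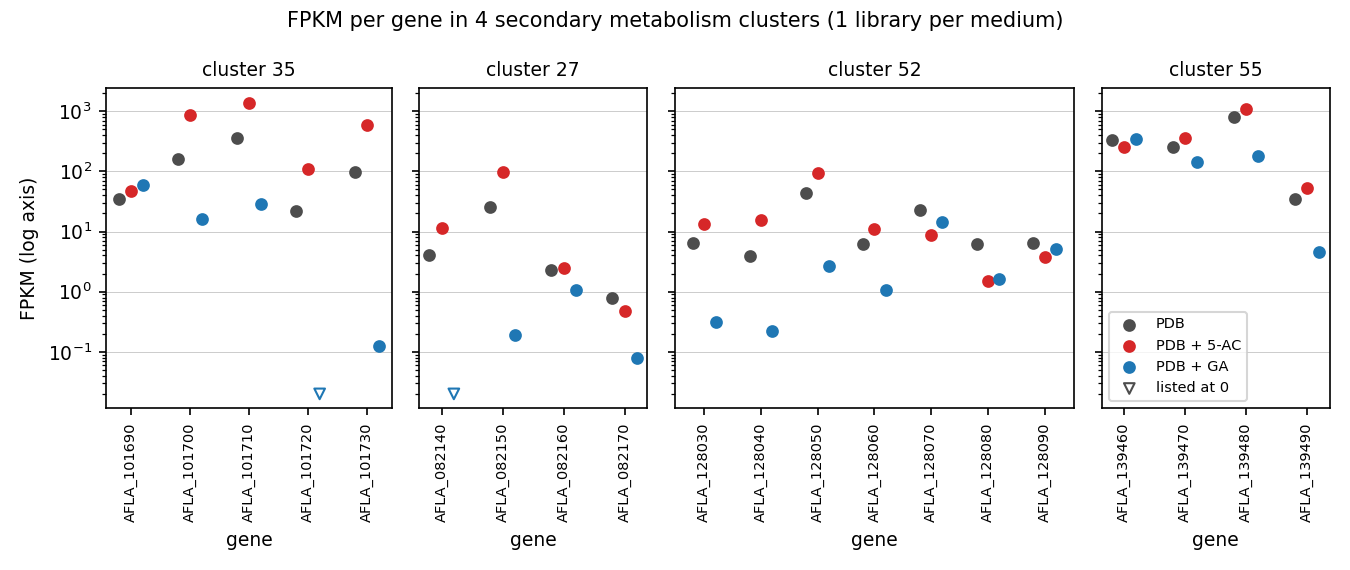
FPKM on a log axis for each gene of clusters 35, 27, 52 and 55 in the 3 libraries, 1 point per library with no error; open triangles at the bottom mark values listed at 0. In cluster 35 the points of 4 genes are ordered 5-AC, PDB, GA from high to low, for example 581, 96.8 and 0.126 FPKM for AFLA_101730.

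Among described genes at 10 FPKM or more, the largest ratios upward with GA belonged to the NRPS-like gene AFLA_118440, from 2.03 to 28.5 FPKM (14.04-fold), and AFLA_090180, from 103 to 796 FPKM (7.70-fold). AFLA_066740 (7.90 to 34.999 FPKM, 4.43-fold), the O-methyltransferase gene AFLA_016120 of cluster 10 (3.83 to 18.3 FPKM, 4.78-fold) and the L-ornithine N5-oxygenase gene SidA, AFLA_047190 (5.46 to 24.0 FPKM, 4.39-fold), came next. SidA catalyses the first step of siderophore synthesis, by which fungi take up iron. The dioxygenase gene AFLA_053810 of cluster 17 (57.4 to 179 FPKM, 3.12-fold), the trihydroxytoluene oxygenase gene AFLA_121450 (20.2 to 59.4 FPKM, 2.95-fold) and the MFS transporter gene AFLA_104230 (8.86 to 25.0 FPKM, 2.82-fold) were also in this set. The authors' deposited table calls AFLA_118440, AFLA_090180, AFLA_066740 and AFLA_047190, with q-values up to 0.0438, and none of the other 4. Downward, the set included the gene of 3-hydroxyanthranilate 3,4-dioxygenase, an enzyme of tryptophan breakdown, AFLA_079310, at 25.9 FPKM in PDB and 0.292 FPKM with GA (88.7-fold lower). It is called in the authors' deposited table with a q-value of 0.00162. Its GA value rests on a few fragments, so the size of the fold is uncertain.

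The aflatoxin cluster (cluster 54, EQ963478, positions 2176420 to 2253102) split into parts. The 26 measured genes had a median log2 ratio of -0.60 with GA (percentile 0.0900), with 10 at least 2-fold lower and none 2-fold higher. With a filter at 5 FPKM the median of the 13 genes that stayed was -0.30 at percentile 8.68, inside the central 95%, and with a pseudocount of 5 that of all 26 was -0.29 at percentile 0.0600. The 20 genes from aflYa to aflH encode many of the enzymes of the pathway. All but one of them were low in every library, at 4.78 FPKM or less in PDB, and the exception was aflNa at 537 FPKM, a locus of 390 bp, under the 430 bp below which FPKM is unstable. Without aflNa, 16 of 19 were lower with GA than in PDB and 14 of 19 lower with 5-AC, and 14 of 19 were lower with GA than with 5-AC. Of the 19, 3 are listed at 0 in PDB and so could not be lower with either agent. With 5-AC, 5 are listed at 0 and could not be lower with GA than with 5-AC. The cytochrome P450 gene aflG went from 3.29 FPKM in PDB to 0.585 FPKM with 5-AC and 0.196 FPKM with GA. The monooxygenase gene aflX had 4.78, 0.866 and 0.442 FPKM, but it shares its locus coordinates with aflW, so the split of fragments between the 2 genes is uncertain. aflG and aflX are the 2 aflatoxin genes called in the authors' deposited table, both with GA. Outside the stretch, the sugar regulator gene aflYd had 10.2, 4.37 and 10.06 FPKM in PDB, 5-AC and GA, aflYe 18.2, 8.70 and 16.1 FPKM, and the reductase gene aflD 5.31, 2.51 and 4.06 FPKM. The transcription activator gene aflR had 27.1, 28.0 and 29.9 FPKM, the pathway regulator gene aflS 35.5, 36.6 and 25.7 FPKM, and the polyketide synthase gene aflC 9.69, 9.34 and 10.5 FPKM. The transmembrane protein gene aflT had 152, 131 and 130.4 FPKM.

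**Figure D3:**
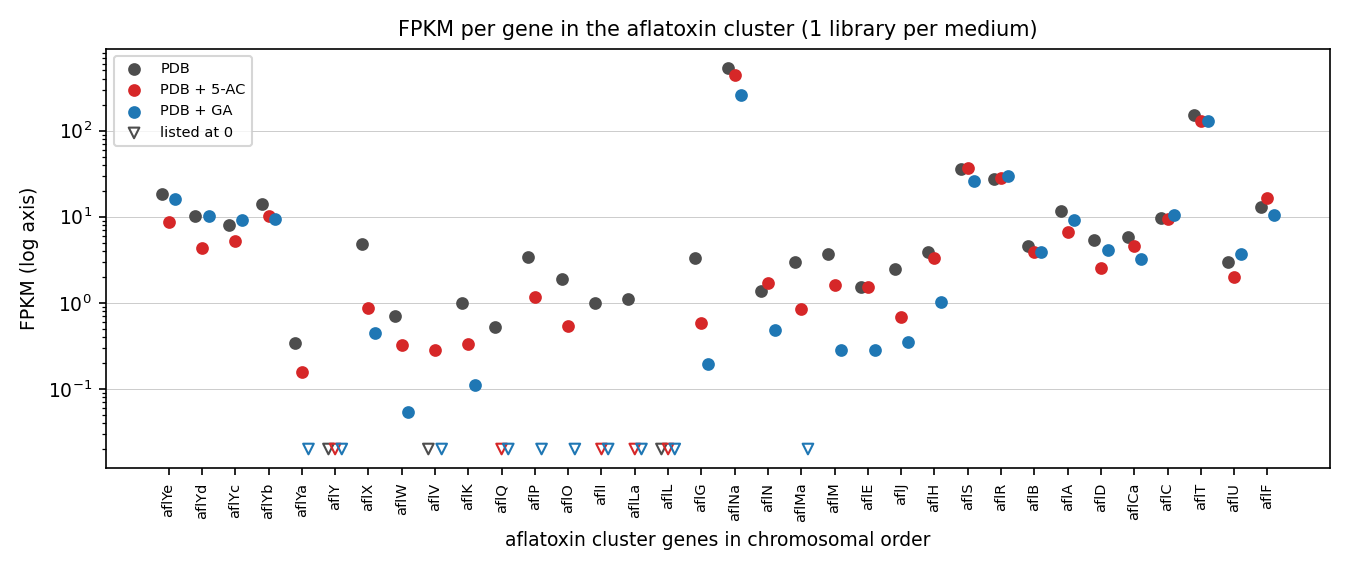
FPKM on a log axis for the 34 aflatoxin cluster genes in chromosomal order, 1 point per library with no error; open triangles mark values listed at 0. The stretch from aflYa to aflH, apart from aflNa, lies at 4.78 FPKM or less in PDB and mostly lower with both agents, while aflS, aflR and aflC on its right lie close together in the 3 libraries.

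Of the other lists with GA, the 3 cyclopiazonic acid genes had a median of -2.17 (percentile 0.0700), with 2 of 3 at least 2-fold lower, and the FAD-dependent oxidoreductase gene AFLA_139470 stood at 257 FPKM in PDB and 143 FPKM with GA. The 3 kojic acid loci had a median of -0.38 (percentile 18.6), with 1 at least 2-fold lower. Of the 15 regulator loci, 12 differed by less than 2-fold and 3 were lower, and their median was 0.20 (percentile 91.4). The locus that was higher with 5-AC was among the lower ones, at 12.5 FPKM in PDB and 1.22 FPKM with GA, and it is called in the authors' deposited table. The 40 backbone enzyme genes had a median of -0.27 (percentile 55.9 among described cluster genes), with 3 higher and 8 lower. The 6 aromatic catabolism genes had a median of 0.27 (percentile 98.0), but they went both ways, from AFLA_053810 at the top to AFLA_079310 at the bottom, with 1 higher and 1 lower by 2-fold. Without a filter the median of 7 genes was -0.0152 at percentile 71.7 and with a pseudocount of 0.1 the percentile was 96.3, both inside the central 95%. The phenol 2-monooxygenase gene AFLA_064250 stood at 122 and 190.4 FPKM. The 14 MFS transporter genes had a median of 0.09 (percentile 91.6) with 3 higher and none lower, and the 13 cytochrome P450 genes one of -0.45 (percentile 21.7) with 1 higher and 4 lower. Inside the central 95% were also the 8 Zn(II)2Cys6 transcription factor genes (-0.20, percentile 35.6), the 3 ABC transporter genes (-0.19, percentile 72.7), the 3 conidiation genes (-0.32, percentile 58.4) and the 3 iron and siderophore genes (0.54, percentile 90.04). None of these 3 iron and siderophore genes differed by 2-fold. The words that drew this list did not pick up the SidA gene AFLA_047190, so its rise with GA is not in that median.

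Compared directly, clusters 35, 27 and 52 and the cyclopiazonic acid genes had lower medians with GA than with 5-AC. Cluster 35 had a median log2 ratio of GA to 5-AC of -5.63, cluster 27 of -3.65, cluster 52 of -2.56 and the cyclopiazonic acid list of -2.59. At least 2-fold lower were 4 of 5 measured genes in cluster 35, 2 of 3 in cluster 27 and 4 of 7 in cluster 52. The other gene of cluster 35, AFLA_101690, went the other way. Its deposited log2 fold change against PDB was 0.759 with GA and 0.431 with 5-AC. The kojic acid loci had a median of 1.05 (percentile 98.5) and 2 of 3 were at least 2-fold higher with GA. Of the 38 clusters, 10 lay below the central 95% of random lists and 2 above it. Over the genome 1284 genes were at least 2-fold higher with GA than with 5-AC and 1104 lower. The median gene lay at 0.18, and with that median set to 0 there were 970 higher and 1359 lower, so the side with more genes turns with the scaling.

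The 2 agents' ratios against PDB were also set against each other. Of the genes past 2-fold, 156 were higher with both agents and 373 lower with both, while 80 were higher with 5-AC and lower with GA and 74 the reverse. Without genes listed at 0, 91 were higher and 280 lower with both. Independent lists of these sizes would share 42.4 genes upward and 111 downward, and 63.3 and 74.6 in the opposite directions, beside the 80 and 74 seen. Both ratios use the same PDB library, which by itself makes them move together and lowers the number of genes in opposite directions. Simulated libraries that differed by counting error alone shared 5.15 genes upward and 1.25 downward on average over 20 draws. Across genes, which are not independent replicates, Pearson's r was 0.30 and Spearman's rho 0.26, against a simulated r of 0.57 from counting error alone and 0.50 for 3 libraries of equal independent spread. The covariance of the ratios was 0.284, against 0.0217 in the simulation of counting error. The spread between cultures is not in that simulation, nor are unstable short loci or failed estimates. PDB has 1 library and cannot be divided, so the shared control may account for part or all of the excess in the same direction. Of all loci, 66 are called in both comparisons in the authors' deposited table, 11 higher in both, 32 lower in both and 23 in opposite directions.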

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

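The tests on cluster 35, on the aflatoxin stretch and without loci under 430 bp were chosen only after the results were seen. Genes that moved in opposite directions with the 2 agents were picked out because the response differed between the treatments. Of the measured genes, 80 were at least 2-fold higher with 5-AC and at least 2-fold lower with GA, and 74 were lower with 5-AC and higher with GA, each against PDB. Independent lists of these sizes would give 63.3 and 74.6. The shared PDB library makes the 2 ratios move together, which lowers the number of genes in opposite directions. These values are therefore too high a baseline, and no other was computed. The differences were not tested, since each medium has 1 library. Among them were 12 cluster genes, 8 of them in 3 clusters: 4 in cluster 35 (AFLA_101700, AFLA_101710, AFLA_101720 and AFLA_101730), 2 in cluster 27 including the polyketide synthase gene AFLA_082150, and 2 in cluster 52 including the efflux pump gene AFLA_128040.

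For cluster 35, 3 technical causes were weighed. Library scaling would show in the median gene, whose log2 ratio of GA to 5-AC was 0.18, and is excluded. Counting error would leave the ratio of GA to 5-AC over the estimated fragments of the cluster near 1, but its upper 95% bound was 0.0357. This argues against counting error alone for the difference between GA and 5-AC. The cluster's differences from PDB were not bounded. The cluster was chosen after its values were seen, and AFLA_101720, listed at 0 with GA, entered as 0 fragments. A PDB library alone out of place would leave the ratio of GA to 5-AC near 1 as well, but without the spread between cultures the bound of 0.0357 cannot tell. The opposite signs of the ratios are what picked the cluster out and test nothing.

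For the aflatoxin stretch from aflYa to aflH without aflNa, counting error was tested on the estimated fragments summed over 19 genes. The ratio of 5-AC to PDB was 0.380 with an upper 95% bound of 0.475, where counting error alone would leave 5-AC and PDB level. The stretch was chosen after its lower values were seen. Loci listed at 0, 3 in PDB and 5 with 5-AC, entered as 0 fragments, and aflW and aflX share a locus. The bound therefore argues against counting error alone but does not exclude it. A PDB library alone out of place would leave 5-AC and GA level. The ratio of GA to 5-AC was 0.270 with an upper bound of 0.392, but without the spread between cultures this test cannot tell whether PDB stood out.

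The excess of lower over higher genes with 5-AC was weighed as well. With the median log2 ratio set to 0 the lower share of 2-fold genes was 46.8%, but centring pulls the split towards even by construction, so this does not show whether scaling was the cause. Without loci under 430 bp the share was 64.3%, so the short loci among the genes counted do not account for it. Their weight in the FPKM scale was not tested.

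Loci without an annotated gene were picked out as signal in data outside the comparisons. The authors' deposited table calls 11 of them for 5-AC against PDB and 31 for GA against PDB. Among 1019 such loci at 1 FPKM or more, 54 were at least 2-fold higher and 141 lower with 5-AC, and 54 higher and 190 lower with GA. These differences were not tested.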

How the results depend on the processing

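Adding loci without a gene, leaving out loci under 430 bp and leaving out genes listed at 0 were chosen only after the data were seen. A count was taken as kept within 1.5 times its value, a list median within its 95% binomial interval, and a correlation or single ratio only when equal. For lists of 3 genes that interval runs from the lowest to the highest member and covers less than 95%. Of the alternatives to summary results, 60 kept the value within its limits and 15 moved it. Of the alternatives to list medians, 108 kept it, 6 moved it and 2 turned its sign, and the 2 alternatives to each of the 40 ratios of described genes picked as the largest moved all 80 values and turned no sign, which a choice by size favours; other named genes were not rerun. Without a filter, the median of the backbone enzymes with 5-AC was -0.0161 in place of 0.14 and that of aromatic catabolism with GA -0.0152 in place of 0.27, over lists that gained genes under 1 FPKM. The correlation of the ratios, 0.301, was 0.348 with a pseudocount of 0.1, 0.277 with a pseudocount of 5, 0.304 without a filter, 0.290 with a filter at 5 FPKM, 0.297 with loci without a gene, 0.230 without loci under 430 bp and 0.197 without genes listed at 0; the cause was not tested. With a filter at 5 FPKM, 1 list in place of 2 lay outside the central 95% for 5-AC, and the list lost was that of the backbone enzymes. For GA the lists outside went from 3 to 2 with that filter, and the list lost was that of the aflatoxin genes (percentile 8.68, 13 genes). Without a filter and with a pseudocount of 0.1 they also went to 2. The list lost there was that of aromatic catabolism (percentiles 71.7 and 96.3). Why these lists moved was not tested. A pseudocount of 5, which shrinks the ratios of low genes by construction, left 919 genes past 2-fold for 5-AC, 1047 for GA, 1382 for GA against 5-AC and 265 in the same direction with both agents. Clusters outside the central 95% numbered 7 to 9 for 5-AC, 10 to 12 for GA and 9 to 13 for GA against 5-AC over the settings run. Without loci under 430 bp, 111 genes were higher and 288 lower with both agents. The 4-fold size, stricter by construction, left 366, 519 and 708 genes. No paired analysis was possible because each medium has 1 library. Depth was low over the aflatoxin stretch from aflYa to aflH, with about 261 estimated fragments over 19 genes in PDB.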

Other observations

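The neighbour and scaffold-end predictions below were written before those tests were run, and the list of runs was drawn up only after the neighbour result was seen. Genes at least 2-fold different often lay side by side with others that moved the same way, also outside the deposited clusters. With GA, 10 neighbouring genes on EQ963477 (positions 2272152 to 2286477) were all at least 2-fold lower, with a median of 19.3 FPKM in PDB and 0.440 FPKM with GA. These genes had a median log2 ratio of -1.01 with 5-AC as well. In addition, 8 genes on the same scaffold (positions 1389127 to 1410633) had medians of 90.7 and 3.33 FPKM. A run of 7 higher genes on EQ963473 (positions 3587227 to 3598275) had a median of 23.4 FPKM in PDB and 229 FPKM with GA. From the dimethylallyl tryptophan synthase gene AFLA_139480 of cyclopiazonic acid synthesis onward, 9 neighbouring genes on EQ963478 (positions 2263610 to 2302374) were lower with GA, and only 2 of them belong to a deposited cluster.

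With 5-AC, 5 neighbouring genes on EQ963472 (positions 2659280 to 2668353), which begin shortly after cluster 27, were higher, with a median of 11.04 FPKM in PDB and 58.7 FPKM with 5-AC. With GA their median was 28.8 FPKM and their median log2 ratio 1.02, unlike cluster 27. On EQ963485 (positions 1447488 to 1461774), 5 genes were lower with 5-AC, with medians of 30.0 and 5.39 FPKM. Their median with GA was 102 FPKM, while their median log2 ratio of GA to PDB was -0.05. These medians need not come from the same gene. On EQ963472 (positions 1873095 to 1880235), 5 genes that end with the 3-hydroxyanthranilate 3,4-dioxygenase gene AFLA_079310 were lower with 5-AC, with medians of 13.4 and 4.41 FPKM, and their median with GA was 0.320 FPKM.

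One hypothesis was that genes respond in runs of neighbours. Pairs of neighbouring measured genes past 2-fold in the same direction numbered 299 with 5-AC, against a mean of 142 and a highest value of 176 in 1000 shuffles of gene order, and 406 with GA, against 165 and 208. Outside the deposited clusters there were 280 pairs with 5-AC (highest shuffle 173) and 363 with GA (highest shuffle 190). Pairs with the same coordinates were left out before counting, and no counted pair overlapped. Fragments that run across close neighbours were not tested. Chance placement is excluded by the shuffles for these libraries, which is consistent with regulation of neighbouring genes together, but the spread between cultures was not measured and the shuffles do not separate an effect of the agents from it.

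A further hypothesis was that the agents act more on genes near scaffold ends. Over 15 scaffolds longer than 1 Mb, 14.7% of 876 genes within 100 kb of an end differed by 2-fold with 5-AC against 15.6% elsewhere, a ratio of 0.944. With GA it was 14.6% against 17.2%, a ratio of 0.849. The hypothesis did not hold for either agent. The far end of a scaffold was taken as the end of its last listed locus. Scaffold ends need not be chromosome ends, which were not tested.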
